A study of Arabidopsis thaliana with 6 samples.

How the data were processed

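RNA sequencing of whole Col-0 seedlings was compared between 3 control samples and 3 samples exposed to Serratia marcescens PLR for 2 days. Per the labels' protocols, total RNA was extracted with Trizol, reverse transcribed with random primers and sequenced on an Illumina HiSeq instrument or another sequencer. The labels do not mention strand marking. The aligner, the counting tool, the genome build and the test behind the table are not given in the sources used here. The labels do not say whether the 3 samples of a group came from separate cultures.

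The data used were 1 deposited table of 2271 genes. The authors had selected these genes: every listed gene has an absolute log2 fold change of at least 1.00 and a q-value of at most 0.001, and genes that failed these limits were not analysed here. Per the file headers, the table gives for each group an average read count, and the values are estimated counts averaged over the group by the authors, since they need not be whole. Of the control means 76.8% and of the Serratia means 74.3% become whole when multiplied by 3 (within 0.005), as means of 3 whole counts do, and 625 genes have at least 1 mean that does not. Of these genes 62.9% have a near-identical copy or an overlapping gene in the reference, against 13.7% of the other genes (Fisher's exact test, two-sided, p = 9.64e-115), and they are described as having fractional means. The deposited expression value of each group is a score here, because the file headers name no unit. It is close to the mean reads divided by transcript length and a constant. The median was 22.5 reads per kilobase and unit of expression in both groups (quartiles 21.5 to 22.8, over the 694 control and 1053 Serratia means used), as reads scaled to transcript length and library size would give. The depth per sample is not known, and precision is given by the counting intervals below.

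The deposited log2 fold change of the authors equals the log2 ratio of the mean reads plus 0.0025 (within 0.01 for all 2231 genes with both means above 0), so the groups were scaled by a depth factor of 1.00, and a mean of 0 was replaced by about 0.166 reads. The p-value and q-value columns were deposited by the authors with 5 decimals. A normal test against counting noise alone, applied to the reads summed over 3 libraries, gave p-values with a median ratio of 0.997 to the deposited ones (5th to 95th percentile 0.672 to 1.19, 314 genes with a p above 0 and both means above 0). With the means taken as the counts of 1 library, the median ratio was 316. Genes with a p written as 0 were not compared. The deposited p-values are therefore described as close to measures of counting noise of pooled reads.

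The tests planned before the data were examined assumed values for each sample, and for a table of selected genes the plan was to take the authors' own calls and to count no genes over the genome. That plan was followed. Folds were computed here as the ratio of the mean reads times the depth factor, with exact (Clopper-Pearson) 95% intervals from the reads summed over 3 libraries and rounded to whole reads. These intervals cover counting error only, since reads without molecular identifiers are not independent molecules. For a group at 0 reads the fold is a lower bound against a floor of 3 counts over the group. This bound leaves out the counting error of the other group, so an interval would reach lower. No test over samples was made.

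Lists of genes were fixed before the data were examined, 28 in number, on auxin repressors, inactivation, short auxin-induced transcripts, synthesis and transport, lateral roots, cell cycle, salicylic acid, jasmonate, ethylene, pattern-triggered immunity, indole and aliphatic glucosinolates, iron, phosphate, nitrate, sulfate, photosynthesis, root cell types, root hairs, suberin, cytokinin, abscisic acid, flavonoids, low oxygen, sugar starvation, detoxification and heat shock. Of 613 entries 587 were matched by locus and symbol, and 26 whose symbol was not found in the reference table were left out and counted. For each list with at least 5 listed members (18 lists), higher against lower members were compared with the rest of the table by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Because 83.6% of the listed genes rose, a list of up to 13 listed members could not pass this test by rising. The list with the most listed members, cell cycle, had 21, all higher. Its unadjusted p was 0.0366 and its adjusted p 0.220 (Fisher's exact test). Lists could therefore pass here only through lower members. A count adjusted over the list alone could not be made, since members outside the table have no p. Genes were named by a rule fixed before the data were examined: the 10 largest rises and the 10 largest falls among genes with at least 10 mean reads in the higher group, up to 4 members of each list with the smallest q-value (ties by fold), and 10 auxin, lateral root and defence genes.

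Gene names and neighbours came from the NCBI annotation of the TAIR10.1 assembly, in which 2268 of 2271 identifiers were found. No coordinates are given, because the build of the table is not named. The symbols of 4 genes, APR1 among them, are calendar dates in the deposited table, and these were named from the reference. A near-identical copy means at least 95% identity over at least 100 nt between the longest transcripts (blastn 2.17.0). Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

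The steps were tested on simulated data. In 2271 simulated genes of the comparison with counting noise alone, 78% of 200 genes changed 2-fold and 90.5% of those changed 4-fold were recovered. The intervals held the true ratio in 95.6% and 95.9% of genes. A gene counted as recovered by its p alone, without the 2-fold limit of the table. The shares recovered therefore do not describe the authors' selection. With a coefficient of variation of 0.2 between samples, the counting test called 15.7% of unchanged genes in the 2-fold simulation, and 44.5% of those with at least 300 reads summed over a group, while 0.435% of unchanged genes were called and also reached 2-fold. Recovery of the 2-fold changes, again by p alone, was then 62%. A coefficient of variation of 0.4 was not simulated, so the share of unchanged genes called at that spread is not known. Of 1000 random lists 2.5% had a p under 0.05. The alternatives tried were a filter of 50 mean reads, a q-value under 0.01, a fold of at least 4, a counting interval beyond 2-fold, a minimum of 10 reads, leaving out genes with fractional means, assumed coefficients of variation of 0.2 and 0.4, other matching and background for the lists, and for named genes a pseudocount of 1 and the expression values.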

Results

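Transcripts were measured by RNA sequencing in whole Arabidopsis thaliana seedlings of the wild type Col-0, the reference accession of the species. The seedlings were 5 days old when they were exposed to the bacterium Serratia marcescens PLR, or left without it, and 7 days old when RNA was taken after 2 days of exposure. The 6 samples formed 2 groups, 3 control and 3 Serratia. The values used here come from 1 table of 2271 genes that its authors had selected as changed, and it gives for each gene the mean estimated read count of each group. Values of single samples were not analysed here, so no mean below has an SD, and the depth of each library is unknown. The means over the table summed to 1510129 reads per library in the control group and to 1142668 in the Serratia group. The bracketed intervals are exact 95% intervals of the ratio from the reads summed over the 3 libraries of a group, and they cover counting error only.

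The comparison asked which transcripts differ in seedlings that grew with the bacterium. In the authors' deposited table, 1899 genes were higher and 372 were lower with Serratia, so 83.6% of the listed genes rose. The table held 8.23% of the protein-coding genes of the reference annotation. The median rise was 2.68-fold and the median fall 2.87-fold. A change of at least 4-fold was reached by 412 of the higher and 117 of the lower genes, and one of at least 16-fold by 58 and 22 genes. The median of the genes that fell was 341 reads in the control and 113 with Serratia, and that of the genes that rose was 29.3 and 84. Of all listed genes, 625 (27.5%) have means that 3 whole counts cannot give, so their estimated counts were not whole, and such means are called fractional below. Not every named gene with a fractional mean is marked as such below. APR1, NIT2 and FRK1 are among those left unmarked. Where they are above 0, the p-values of the authors' deposited table lie close to those of a test against the counting noise of the pooled reads, which does not measure the spread between seedling samples. With an assumed biological coefficient of variation of 0.4 between samples, 579 of the 2271 genes would pass the same p.

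**Figure D1:**
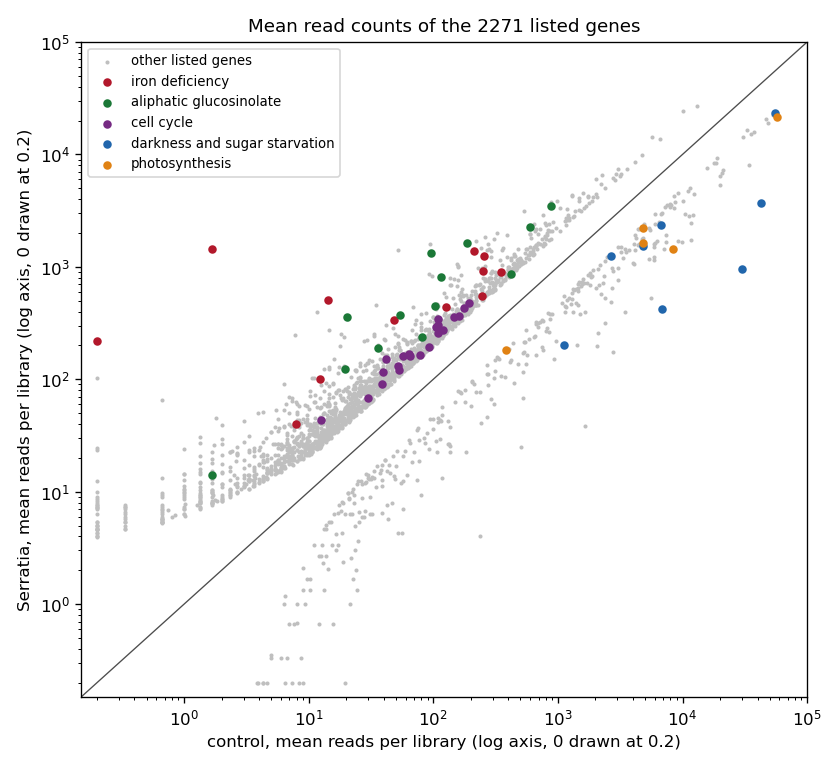
Mean estimated reads per library in the control group (x axis) and the Serratia group (y axis), both on log axes, for the 2271 listed genes, with a mean of 0 drawn at 0.2 and the diagonal marking equal reads. The coloured points are listed members of 5 gene lists: the iron, glucosinolate and cell cycle genes lie above the diagonal, and the starvation and photosynthesis genes lie below it.

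The 10 largest rises ranged widely in read number. IRT1, the main iron transporter of the root surface, rose from 1.67 to 1439 mean reads, 865-fold (370 to 2664). CYP82C4, an oxidase of coumarin synthesis in iron-starved roots, had no control reads and 218 mean reads with Serratia, at least 218-fold higher when the control is set to the 3 counts over the group that a count of 0 allows. FRO2, the ferric reductase that works with IRT1, rose from 14.3 to 507 reads, 35.5-fold (26.2 to 49.2). DFR, an enzyme of anthocyanin synthesis, rose from 0.667 to 65.7 reads, 98.6-fold (27.0 to 820). AT1G66090, which encodes a disease resistance protein of the TIR-NBS class, rose from 11.7 to 399 reads, 34.2-fold (24.5 to 49.4). The ranking follows the log2 fold change of the authors' deposited table, in which a mean of 0 counts as about 0.166 reads, and the other 5 of its 10 largest rises had 0 control reads. They were RFC3, a replication factor subunit, at least 102-fold higher, AT4G12495 at least 24.2-fold, the chalcone synthase family gene AT4G00040 at least 23.57-fold, AT2G32200 at least 12.3-fold and the transcription factor gene AT1G33760 at least 10-fold higher. By these bounds the last 4 would rank below CYP71A12, at 31.7-fold, which itself has fractional means. CYP82C4, RFC3, AT4G12495 and AT4G00040 have fractional means, and RFC3 and AT4G12495 overlap a neighbouring gene in the reference.

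Among the 10 largest falls, ASN1, the asparagine synthetase that darkness and low sugar induce, fell from 29894 to 958 mean reads, 31.2-fold (30 to 32.4). BCAT-2, a branched-chain amino acid transaminase gene with fractional means, fell from 6795 to 419 reads, 16.2-fold (15.3 to 17.2). DOG1, a regulator of seed dormancy, fell from 12.0 to 0.667 reads, 17.96-fold (4.63 to 154). The late embryogenesis gene LEA7 fell from 21.3 to 1 read, 21.3-fold (6.97 to 106), and the seed maturation gene AT2G21820 from 24.3 to 1.33 reads, 18.22-fold (6.82 to 68.6). AT4G25580, annotated as a CAP160 protein, fell 42.8-fold (35.6 to 51.9) and the cold acclimation gene AT4G37220 fell 20.1-fold (15.96 to 25.7). AT5G24640, of no described function and with fractional means, fell 59.0-fold (33.6 to 115), and the kinase-related gene AT1G63590 fell 23.4-fold (6.14 to 199). RLP40, a receptor-like protein gene, had 19.4 control reads and none with Serratia, at least 19.4-fold lower, and has fractional means.

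Genes of the darkness and sugar starvation response fell together. Of 12 matched members 8 were listed and all 8 were lower, with a median fall of 4.16-fold. Besides ASN1 and BCAT-2, SEN1, a senescence-associated gene, fell from 42461 to 3730 reads, 11.4-fold (11.1 to 11.6), and the beta-glucosidase gene BGLU30 from 1113 to 201 reads, 5.54-fold (5.08 to 6.05). The list differed in direction from the rest of the table (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted p = 8.76e-06 over 18 lists). This test treats genes as independent of each other, although genes of a shared response can move together. Its p covers no spread between samples, here and for the lists below. Since most genes of the table rose, no list could pass here by rising. The photosynthesis list was the other list to pass. Of its 42 members 5 were listed, all 5 encoded light-harvesting proteins of photosystem II, and all were lower (Fisher's exact test, adjusted p = 0.00104). LHCB1.4 fell from 8428 to 1456 reads, 5.78-fold (5.60 to 5.97), LHCB1.1 fell 2.96-fold (2.86 to 3.06), LHCB1.5 fell from 57050.3 to 21554 reads, 2.64-fold (2.62 to 2.67), and LHCB3 fell 2.19-fold (2.12 to 2.25). All 5 have fractional means, and these genes belong to a family of similar sequences, so how much each member fell is uncertain. Without genes of fractional means the list has no listed member and no test.

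Iron deficiency genes rose. Of 20 matched members 12 were listed and all 12 were higher, with a median rise of 5.81-fold. They included, besides IRT1, FRO2 and CYP82C4, NAS2, which makes the iron chelator nicotianamine, at 12.3 control and 99.7 Serratia reads, 8.09-fold higher (5.74 to 11.7). Of the 12, 8 have fractional means. Matched by locus alone, 16 of 27 members were listed and all 16 were higher. Sulfate starvation genes were also higher in 7 of 7 listed members, out of 12 matched. LSU2 rose from 33.3 to 243 reads, 7.29-fold (5.91 to 9.08), APR1, a reductase of sulfate assimilation, rose from 273 to 1597 reads, 5.86-fold (5.44 to 6.32), the glutathione-degrading enzyme gene GGCT2;1 rose 3.86-fold (2.97 to 5.06), and SDI1 rose 2.4-fold (1.73 to 3.37). The nitrate list had 6 of 20 members listed, 4 higher and 2 lower. The nitrate reductase gene NIA1 fell from 48255 to 18850 reads, 2.56-fold (2.53 to 2.58), BT1 fell 2.67-fold (2.59 to 2.76), the regulator HRS1 rose 3.3-fold (2.99 to 3.66) and RFNR2, a root ferredoxin reductase, rose 2.43-fold (2.25 to 2.62). Of 21 phosphate starvation genes 2 were listed, NPC4, 4.28-fold higher (2.84 to 6.66), and PS2, 2.78-fold lower (2.23 to 3.5). The direction of these lists did not pass the test against the rest of the table. The adjusted p was 0.577 for iron, 0.841 for sulfate and 0.577 for nitrate (Fisher's exact test). Most genes of the table also rose, so lists of these sizes could not pass by rising. With all listed members higher, the unadjusted p was still 0.235 for iron and 0.607 for sulfate (Fisher's exact test). The phosphate list was too small to test.

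**Figure D2:**
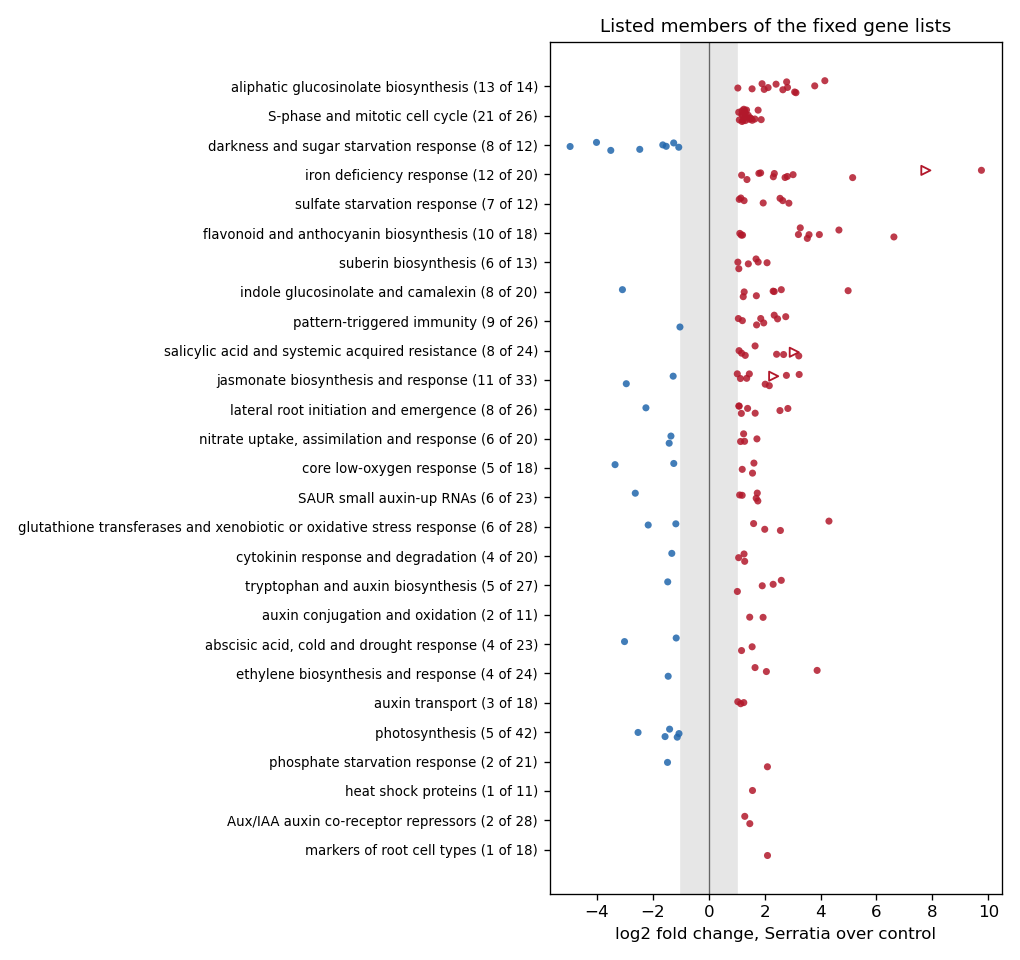
Log2 fold change, Serratia over control, of each listed member (points) of the 27 gene lists with a listed member, red for higher and blue for lower, with listed and matched members in brackets on the y axis. Open triangles mark genes with 0 control reads at their lower bound, and the grey band marks changes under 2-fold, which the table does not hold. The 8 starvation genes and the 5 photosynthesis genes lie to the left, and the 21 cell cycle genes and the 13 aliphatic glucosinolate genes lie to the right.

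Aliphatic glucosinolates are sulfur-rich defence compounds made from methionine, and 13 of the 14 matched genes of their synthesis were listed, all higher, with a median rise of 6.28-fold. MAM3, which elongates the methionine chain, rose from 20.3 to 361 reads, 17.8-fold (13.7 to 23.4), CYP79F1 from 96.6 to 1335 reads, 13.8-fold (12.3 to 15.6), BCAT4 from 187 to 1625 reads, 8.69-fold (7.96 to 9.50), and the transcription factor gene MYB76 from 1.67 to 14.0 reads, 8.41-fold (3.33 to 27.3). Of the 13, 8 have fractional means. The list of indole glucosinolate and camalexin genes, which are made from tryptophan, had 8 of 20 members listed, 7 higher and 1 lower. Of the 8, 5 have fractional means. CYP79B2 rose from 242 to 1459 reads, 6.04-fold (5.58 to 6.54), and the regulator MYB51 from 167 to 847 reads, 5.07-fold (4.60 to 5.59). CYP71A12 rose from 7.83 to 248 reads, 31.7-fold (21.4 to 51.4), while CYP71A13 fell from 21.8 to 2.56 reads, 8.51-fold (3.88 to 19.6). Both have fractional means and belong to the same gene subfamily, so their opposite directions are uncertain. Neither list passed the test of direction against the rest of the table (Fisher's exact test, adjusted p = 0.577 and 1). Lists of these sizes could not pass by rising, since most genes of the table rose. With all 13 higher, the aliphatic list had an unadjusted p of 0.144 (Fisher's exact test).

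Flavonoid and anthocyanin genes rose, with 10 of 18 matched members listed and all 10 higher, by a median of 10.6-fold. After DFR, LDOX, the next enzyme of anthocyanin synthesis, rose from 1.80 to 45.3 reads, 25.2-fold (11.4 to 85.3), the glycosyltransferase gene UGT79B1 from 1.33 to 20.7 reads, 15.5-fold (5.77 to 58.8), and MYB75, a transcription factor that turns the pathway on, from 1.33 to 16 reads, 12.0-fold (4.40 to 45.9). LDOX has a near-identical copy in the reference and a fractional mean, and UGT79B1 has such a copy but no fractional mean. All 6 listed members of the suberin list, out of 13 matched, were higher, among them FAR5, 4.24-fold (3.5 to 5.17), CYP86B1, 3.4-fold (3.0 to 3.87), ABCG6, 3.23-fold (2.97 to 3.51), and KCS2, 2.67-fold (2.43 to 2.92). The adjusted p was 0.689 for flavonoids and 0.841 for suberin (Fisher's exact test). Neither list could pass by rising, since most genes of the table rose as well.

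Most members of the lists of salicylic acid, jasmonate, pattern-triggered immunity and ethylene were not in the table. Over all 28 lists, 174 of 577 distinct matched members (30.2%) were listed, against 8.23% of the protein-coding genes of the reference. Most of the listed members of these 4 lists were higher, as were most genes of the table. On the salicylic acid list 8 of 24 members were listed, all higher. PBS3, an enzyme of salicylic acid synthesis, rose from 3.33 to 31.0 reads, 9.32-fold (4.85 to 20.1), FMO1 6.4-fold (3.54 to 12.5) and SARD1 5.38-fold (3.3 to 8.68), and WRKY38 had 8.33 reads with Serratia and none in the control, at least 8.33-fold higher. The marker PR1 was not in the table. On the jasmonate list 9 of 11 listed members were higher, out of 33. LOX4 rose from 16 to 150.3 reads, 9.41-fold (6.98 to 13.0), LOX2 6.86-fold (6.22 to 7.58) and VSP1 4.05-fold (3.4 to 4.88), TAT3 fell 7.74-fold (2.74 to 30.2), and PDF1.2A had 5 reads with Serratia and none in the control, at least 5-fold higher. Of 26 genes of pattern-triggered immunity 9 were listed, 8 higher. WRKY53 rose 6.75-fold (4.83 to 9.5), WRKY33 from 1303 to 4257 reads, 3.27-fold (3.16 to 3.39), and the receptor kinase gene FRK1 from 7.67 to 27.8 reads, 3.63-fold (2.26 to 6.01). On the ethylene list 4 of 24 members were listed, 3 higher and 1 lower. The genes of the hormone-making enzyme ACS11 and ACS6 rose 14.7-fold (6.49 to 41.1) and 3.15-fold (2.99 to 3.32), ERF1 rose 4.17-fold (1.67 to 12.4), and ACS2 fell 2.74-fold (2.04 to 3.72). Matched by locus alone, 5 of 25 members were listed, 3 higher and 2 lower (Fisher's exact test, adjusted p = 0.453), and the added gene, ACO3, fell from 308 to 102 reads, 3.02-fold (2.65 to 3.45). The directions gave an adjusted p of 0.689 for salicylic acid, 0.898 for jasmonate and 1 for pattern-triggered immunity (Fisher's exact test). Lists of these sizes could not pass by rising, since most genes of the table rose. The ethylene list as first matched was too small to test.

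Cell division genes rose by modest factors. Of 26 matched genes of S phase and mitosis 21 were listed and all 21 were higher, with a median rise of 2.48-fold. The replication gene MCM6 rose from 41.7 to 153 reads, 3.67-fold (3.0 to 4.51), PCNA1, the replication clamp, from 109 to 342 reads, 3.14-fold (2.77 to 3.57), and the mitotic cyclin genes CYCB2;1 and CYCB1;1 rose 3.4-fold (2.35 to 5.02) and 2.94-fold (2.38 to 3.65). The list differed from the rest of the table at an unadjusted p of 0.0366 but not after adjustment (Fisher's exact test, adjusted p = 0.220). All 21 were already higher, so the test could give no smaller p for a rise.

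Genes of lateral root formation, the process by which new roots branch from the main root, were listed for 8 of 26 members, 7 higher and 1 lower. MYB77, a transcription factor that acts with auxin response factors, rose from 258 to 1831 reads, 7.11-fold (6.59 to 7.68), LBD29 from 2 to 11.7 reads, 5.84-fold (2.43 to 17.0), and LBD18 from 13.0 to 41.0 reads, 3.16-fold (2.19 to 4.65). EXPA17, a cell wall expansin gene, fell from 106 to 22.3 reads, 4.75-fold (3.64 to 6.28). LBD16 and GATA23 were not in the table. Among genes of tryptophan and auxin synthesis 5 of 27 were listed, 4 higher. Of the 5, 4 have fractional means. CYP79B2 and CYP79B3 are also members of the indole glucosinolate and camalexin list above, so the 2 lists are not separate. Besides CYP79B2, CYP79B3 rose 4.93-fold (4.63 to 5.26), YUC5, which makes auxin, rose from 8.33 to 31.3 reads, 3.77-fold (2.4 to 6.11), and the nitrilase gene NIT2 fell from 3329 to 1200.47 reads, 2.77-fold (2.66 to 2.88). TAA1 and YUC8 were not in the table. Of 28 Aux/IAA repressor genes, which auxin itself induces, 2 were listed, IAA19, 2.77-fold higher (1.93 to 4.04), and IAA3, 2.44-fold higher (2.17 to 2.75). Of 11 auxin-inactivating genes GH3.1 and GH3.2 were listed, 3.85-fold (2.57 to 5.91) and 2.76-fold higher (2.37 to 3.2), and GH3.3 was not. Of 18 auxin transport genes 3 were listed, WAG2, WAG1 and PIN5, higher by 2.38-fold (1.81 to 3.2), 2.21-fold (1.61 to 3.06) and 2.05-fold (1.77 to 2.39). The SAUR genes, short auxin-induced transcripts, had 6 of 23 members listed, 5 higher and 1 lower, with SAUR64 at 3.38-fold (2.18 to 5.40) and SAUR72 at 2.29-fold (1.91 to 2.75). The lower member, SAUR61, named after its values were seen, fell from 10.3 to 1.67 reads, 6.19-fold (2.39 to 20.4). The lateral root, auxin synthesis and SAUR lists gave adjusted p = 1, 0.841 and 1 (Fisher's exact test). Lists of these sizes could not pass by rising, since most genes of the table rose. The other 3 auxin lists were too small to test. A gene outside the table had either missed the authors' thresholds or too few reads, and these cases cannot be told from each other here.

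The remaining lists had few listed members. The glutathione transferase and oxidative stress list had 6 of 28, 4 higher and 2 lower, with GSTU12 up from 2 to 39.3 reads, 19.7-fold (8.79 to 54.8), GSTU20 up 5.91-fold (5.61 to 6.24) and the alternative oxidase gene AOX1D down 4.49-fold (2.67 to 7.96). Matched by locus alone it had 7 of 29, 4 higher and 3 lower (Fisher's exact test, adjusted p = 0.348). The low-oxygen list had 5 of 18, 3 higher and 2 lower, with AT1G19530 down from 2041 to 199 reads, 10.2-fold (9.39 to 11.1), and SUS4 up 3.06-fold (2.06 to 4.66). Both gave an adjusted p of 0.577 (Fisher's exact test). Of 23 abscisic acid, cold and drought genes 4 were listed, RD29B down 8.08-fold (5.12 to 13.4), RAB18 down 2.24-fold (2.13 to 2.36), and KIN1 and RD22 up 2.93-fold (1.99 to 4.31) and 2.25-fold (2.13 to 2.38). Of 20 cytokinin genes 4 were listed, CRF6 down 2.5-fold (2.36 to 2.65) and ARR16, CKX1 and CKX3 up between 2.1-fold and 2.44-fold. Among 18 markers of root cell types WOX5, of the root stem cell centre, was listed, up from 4.33 to 18.33 reads, 4.24-fold (2.29 to 8.46). HSFA2 was the listed member of 11 heat shock genes, up 2.92-fold (2.39 to 3.59), and 0 of 11 root hair genes were listed. The abscisic acid, cytokinin, root cell type, heat shock and root hair lists had fewer than 5 listed members and were not tested as lists.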

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

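Except for the filter of 50 mean reads and the q-value under 0.01 on the gene counts, the alternatives here were chosen after the data had been seen. The q-value limit could remove no gene, since the table holds none above 0.001, and the authors' own calls are the reported result. Of the 2271 genes, all at least 2-fold changed, 1257 had at least 50 mean reads over the 6 samples (80.9% higher), 1342 had a counting interval wholly beyond 2-fold (79.4% higher) and 529 changed at least 4-fold (77.9% higher). These are smaller because each setting keeps fewer genes. With an assumed coefficient of variation of 0.4 between samples, 579 genes passed (76.5% higher), and with 0.2, 2032. Without genes of fractional means 1646 genes were left (85.2% higher), and with at least 10 reads in the higher group 2137. More genes were higher than lower in each of these settings. Sugar starvation and photosynthesis passed with members matched by locus alone, with the other lists as background and with at least 50 mean reads. In these settings both lists kept the same 8 and 5 listed members, all lower. Only the genes they were compared with, or the number of lists in the adjustment, could differ. Without genes of fractional means 1 list passed, sugar starvation, since no listed photosynthesis gene was left. Of the 188 named genes or list members with reads in both groups, 0 moved beyond their counting interval with 1 read added to both means, which cannot turn a direction. The other 11 have a group at 0 and an interval without an upper bound, so this could not move them. Of 188 with expression above 0 in both groups, 0 changed direction with the expression values and 4 moved beyond their counting interval. Not run, because they need values of each sample or genes outside the table, were the other size factors, the unfiltered table, the other count tests, the smaller pseudocount, leaving out each sample, the estimated correlation and the rotation test of lists. No paired analysis was possible because the table holds 1 mean per group. Depth limits low genes most: a listed gene with 2 control counts over the group, such as DFR, has an interval from 27.0 to 820.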

Other observations

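The tests of annotation terms, of fractional means, of freed reads, of the share of higher genes by read number and of tissue share were chosen after the results had been seen. The tests of neighbouring genes, clock genes and ferritin were set down before their values were seen. Genes and terms in the next 2 paragraphs were chosen after their values were seen.

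Genes of the breakdown of branched-chain amino acids were lower with Serratia. All 12 listed genes of the KEGG pathway for valine, leucine and isoleucine degradation fell, against 421 higher and 80 lower among the other 501 listed genes with a KEGG pathway (Fisher's exact test, two-sided, adjusted p = 2.14e-08 over 36 pathways). Besides BCAT-2, these include both subunits of methylcrotonyl-CoA carboxylase, MCCA, from 9889 to 1668 reads, 5.92-fold (5.74 to 6.10), and MCCB, 4.77-fold (4.60 to 4.94), and the dehydrogenase subunits DIN4, 4.60-fold (4.43 to 4.77), and BCE2, 3.89-fold (3.74 to 4.04). IVD, the next dehydrogenase of leucine breakdown, fell from 6211 to 1712 reads, 3.62-fold (3.51 to 3.74). Genes annotated as responding to absence of light had 3 higher and 11 lower members (adjusted p = 7.08e-05 over 109 processes, Fisher's exact test). DIN4, BCE2 and ASN1 are among them. Genes annotated to embryo development ending in seed dormancy had 11 higher and 11 lower members (Fisher's exact test, adjusted p = 0.0125), and those annotated to response to abscisic acid had 34 higher and 19 lower (adjusted p = 0.0143). Genes annotated to the mitochondrion had 25 higher and 28 lower members (Fisher's exact test, adjusted p = 8.25e-09 over 45 components). In all, 13 of 109 processes, 6 of 36 pathways and 6 of 45 components passed the test, and not all of these are named. The tests of terms also treat genes as independent and cover no spread between samples.

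Further genes of the cell cycle, of DNA replication and of kinesins rose. Genes annotated to the cell cycle had 55 higher members and 1 lower (Fisher's exact test, adjusted p = 0.0125). Of these, 39 lie outside the fixed cell cycle list, 38 of them higher, though the test includes the others. All 32 listed genes annotated to DNA replication were higher (Fisher's exact test, adjusted p = 0.0358), and 26 of them lie outside the fixed cell cycle list, though the test includes the others. All 37 listed genes annotated to microtubule-based movement were higher (Fisher's exact test, adjusted p = 0.0225). These 37 are not all division genes: MRH2 is a kinesin of root hairs, and KIN1 is the cold-induced gene counted above. Related terms with all their listed genes higher did not all pass. The adjusted p (Fisher's exact test) was 0.117 for the 19 genes of the KEGG pathway of DNA replication. It was 0.354 for the 16 genes of DNA replication initiation and 0.0843 for the 27 genes of the kinesin complex. HIK, a kinesin of the dividing cell plate, rose from 52.7 to 193 reads, 3.68-fold (3.08 to 4.41), and the kinesin genes POK1 and POK2, which help to place that plate, rose 3.34-fold (2.32 to 4.91) and 4.74-fold (3.08 to 7.54).

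Iron deficiency genes were higher with Serratia, and a lower iron supply or uptake in the treated seedlings may be the source. Ferritin genes, which iron raises, should then be lower. Of 4 ferritin genes 1 was listed, and it was lower: FER1 fell from 7914 to 3644 reads, 2.17-fold (2.12 to 2.22). This goes with the hypothesis, on 1 gene. Iron in the seedlings was not measured here, and a direct signal from the bacterium stays open and untested.

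Sugar starvation genes were lower with Serratia. A smaller share of green tissue in the treated seedlings stays open. One share would lower green-tissue genes by at most one factor. The 5 listed light-harvesting genes, their reads summed, fell 2.79-fold (2.77 to 2.81), and most of these reads are of LHCB1.5. Of the 8 starvation genes, 5 had counting intervals wholly above that fall (ASN1, BCAT-2, SEN1, BGLU30 and TPS11). Of the others, 1 overlapped it (AKINBETA1) and 2 lay below it (DIN10 and TPS10). The median fall was 4.16-fold for all 8 and 2.64-fold for the light-harvesting genes (exact Mann-Whitney test, two-sided, p = 0.222). This does not decide the question, since both sets hold only genes past the 2-fold limit of the table. For the same reason, the 2.79-fold fall is not a measure of green tissue as a whole. The falls of ASN1, BCAT-2 and SEN1, at least 11.4-fold, exceed that of every listed light-harvesting gene, but these are the largest of the list. The other 37 of 42 photosynthesis genes were not in the table, and their values were not analysed here. Of the genes annotated to green tissue processes, those of photosynthesis had 5 higher and 5 lower members (Fisher's exact test, adjusted p = 0.120), those of the chloroplast thylakoid membrane 9 and 6 (adjusted p = 0.0907), and those of the chloroplast 94 and 22 (adjusted p = 0.606). A different hour of harvest in the 2 groups also stays open: of 25 clock genes 6 were listed, LHY 2.85-fold higher (2.01 to 4.1) and the other 5 lower, among them PRR7, 4.33-fold (3.98 to 4.72), where 3 to 7 listed genes had been set as undecided, and genes annotated to circadian rhythm had 5 higher and 9 lower members (Fisher's exact test, adjusted p = 0.00521 over 109 processes). A change in carbon supply by the bacterium is a biological explanation that may apply and was not tested.

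More listed genes were higher than lower. Reads freed by listed genes that fell could raise all other genes. The larger shift under 2 readings of the expression unit was 0.025 on the log2 scale (0.013 under the other), far under the 2-fold limit of the table. By these readings the listed genes held 6.70% or 4.45% of the control total and 5.07% or 3.61% of the Serratia total. With shares this small, the listed genes could not have given a shift near that limit, whatever their falls. Genes outside the table could add to the shift and were not weighed. An excess only among genes with few reads is argued against by the 567 genes with the most reads, of which 66.8% were higher (62.8 to 70.7, exact 95% interval). This was the lowest share among 4 groups of about equal size by mean reads, and the groups with fewer reads had 92.1%, 91.5% and 84.0% higher genes. A real excess of rises with Serratia stays open, as a hypothesis.

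There were 4 genes with 0 reads in the control and at least 20 mean reads with Serratia, CYP82C4, RFC3, AT4G12495 and AT4G00040. Division of reads among similar or overlapping genes may have set their 0: all 4 have means that 3 whole counts cannot give, against 537 of 1936 other genes with at least 20 reads (27.7%, Fisher's exact test, two-sided, p = 0.0060). This holds for the limit of 20 reads: of the 36 genes at 0 in one group with fewer reads in the other, 7 (19.4%) have fractional means, and of all 40 genes at 0 in one group 11 do (27.5%), which is no more than in the whole table. A near-identical or overlapping gene was found for 2 of the 4, against 27.4% of the others (p = 0.303, Fisher's exact test), which does not decide it. IRT1 and FRO2, whose means are not fractional, rose as well, so the rise of iron genes does not rest on CYP82C4.

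In the authors' deposited table, p divided by q was between 53.2% and 54.3% for the 15 genes with the largest q. If q is a Benjamini-Hochberg value, about 53.6% of all tested genes had a p at or below that of these genes. This cannot be read as the share of genes that respond to Serratia, because the p-values cover no spread between samples. In the simulation of 2-fold changes with a coefficient of variation of 0.2, 15.7% of unchanged genes were called. Among those with at least 300 reads summed over a group it was 44.5%.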
